A study of Arabidopsis thaliana with 12 samples.

How the data were processed

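The 12 samples were total RNA from roots of Arabidopsis thaliana Col-0 at a labelled stage of 3.90 weeks. Per the labels, seeds germinated on 0.7% agarose and the plants then grew in hydroponic culture that was not kept sterile, in a nutrient solution at reduced strength. RNA was extracted with the Qiagen RNeasy kit, labelled with biotin by the 3' IVT procedure and hybridised to Affymetrix ATH1 arrays, 1 per sample. The samples form 4 groups of 3: pH 4.5 and pH 6, each at 1 h and at 8 h. The labels give a stock pH of 5.6 for all 12 samples. They do not state the pH of the culture before the treatment or the hour of the day at sampling.

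The values are signal intensities on a linear scale, made by the authors with MAS5 and GCOS per the submitters' processing notes, which state no version. As deposited, each array has a mean of 100 once the highest and lowest 2% of its signals are left out, and no further normalization between arrays was seen in the values. The table has 22810 probe sets, of which 64 are array controls. All values were above 0, and no probe set had identical values on 2 arrays. The probe table given with the series names 1 gene for 13513 probe sets and several for 503, and lists 8730 non-control probe sets under no gene. Gene names came from the RefSeq table of assembly TAIR10.1, matched for 13436 probe sets by gene number. This gave 13286 genes, 11751 of them with a locus code as their only name. No coordinates are given, since the value files name no genome build.

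Signals were analysed as log2(signal + 3.92), the constant being 10% of the median signal. Folds and log2 differences are on this scale, which understates changes of genes near or under the constant. Control probe sets and those with a mean under the 30th percentile, which corresponds to a signal of 10.4, were left out, and 15922 probe sets, among them 8755 that name a single gene and 8664 such genes, were tested. Limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 12 arrays (lmFit, and eBayes with an intensity trend; 8 residual degrees of freedom, median prior degrees of freedom 9.93). The 5 contrasts were pH 6 minus pH 4.5 at 1 h and at 8 h, the difference between these effects, and 8 h minus 1 h at pH 4.5 and at pH 6. P-values are two-sided and adjusted over all probe sets by the Benjamini-Hochberg method at 0.05. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.

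Gene lists were tested with camera of limma, with a preset correlation of 0.01 between genes, on 1 probe set per gene (the one with the highest mean), for lists with at least 5 measured members. Camera with an estimated correlation and fry were run beside it, and p-values were adjusted over the lists of a kind within a comparison. The 35 fixed lists, the contrasts, the tests and the rule for naming genes were written before the data were examined. Since the probe table names few of their genes, 84 of the 561 loci in these lists had a named probe set and 5 lists could be tested: auxin response, calcium and touch, expansins, XTH genes and class III peroxidases. For this reason 32 lists were added after the probe annotation and array summaries were seen, but before any test, and 28 of them could be tested. The added lists are therefore less independent of the material than the fixed ones.

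Named genes were chosen by rule: in each pH comparison the 10 largest differences in each direction, and in each time comparison the 6 largest, among genes past the threshold whose 3 arrays in one group all lay above the 3 in the other. Chance gives such a separation to 10% of genes. For the difference between the pH effects the 6 largest in each direction were taken without that condition. Up to 4 members past the threshold were added for each list that was shifted or had at least 3 such members. In all the rule named 216 genes. Outside the rule, WRKY53, WRKY22 and STZ are named as examples of their list, chosen after their values were seen. The rule also fixed 15 genes of interest whatever their values, and 0 of them had a named probe set, so these are not analysed here. Of the named genes, 38 had a group mean under a signal of 10.4. Below, this is marked for the genes with the largest differences but not for every list member. Unmarked members with such a mean include GH3.1, XTH21, AT2G22880, AT2G39040 and AT5G51490. Of the genes tested, 89 kept more than 1 probe set, and more than 1 was called in 0 to 9 of them per comparison, too few to compare directions.

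The procedure was tested on simulated data with the spread of these arrays and independent noise in each probe set. The simulation therefore does not show how list calls behave when genes are correlated. Of 50 probe sets with a simulated log2 difference of 1, the test found 88% and 92% in the pH comparisons, 52% for the difference between the effects, and 82% and 88% in the time comparisons. At a difference of 0.5 it found 26%, 38%, 4%, 38% and 48% in the same order. False calls numbered 6 to 10 per comparison, among 130 to 171 calls over 15922 probe sets. A shifted fixed list was found in each of the 4 comparisons, and 1 unshifted fixed list was called in the pH comparison at 1 h. Of the 28 added lists, unshifted as well, 1 was called in the time comparison at pH 6.

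Alternatives planned in advance were a constant of 1% or 25% of the median, no filter or a filter at the 50th percentile, quantile normalization, centring on the array median, eBayes without trend, array weights, a replicate block, only unique probe sets, only the arrays compared, and leaving out each array in turn. For lists, an estimated correlation, fry and the mean of a gene's probe sets were planned as well. Chosen after the data were seen were the spike-in signal of each array as a covariate, and the omission of 1 array from each of the 2 groups whose spike-in signals spread most. In the pH 4.5, 1 h group this was replicate 3, the lowest and furthest from the others. In the pH 6, 8 h group it was in turn replicate 1, the lowest, and replicate 2, the furthest from the others.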

Results

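Gene expression was measured in roots of Arabidopsis thaliana, accession Col-0, grown in hydroponic culture at 23 °C and held at pH 4.5 or pH 6 for 1 h or 8 h. The series addresses how roots respond at the transcript level to the pH of the medium. No group was sampled before the treatment, so the pH comparisons do not show at which pH a gene changed. Each of the 4 combinations of pH and time was measured on 3 Affymetrix ATH1 arrays, so every group mean below has n = 3 and the 12 arrays share no sample. The values are array signals, each array scaled to a trimmed mean of 100, with medians between 38.2 and 40.2. The number of arrays limits the precision, and the median standard error of a log2 difference between 2 groups was 0.14. Across probe sets, which are not independent replicates, arrays of the same group correlated at 0.976 to 0.989 and arrays of different groups at 0.921 to 0.967. The first 3 principal components held 36.2%, 26.3% and 11.1% of the variance. The labels do not say whether replicates came from separate cultures. The p-values then measure only the spread between these samples, which may be technical.

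After 1 h, genes of the cell wall and calcium-binding proteins were among the named genes with the largest differences between the pH values. EXPA9 (AT5G02260), an expansin of the class that loosens cell walls, had a signal of 130 ± 4.76 (SD, n = 3) at pH 6 and 12.9 ± 2.59 at pH 4.5, a log2 difference of 3.00 ± 0.14 (SE, adjusted p = 9.96e-11). EXPB1 (AT2G20750), a beta-expansin, was 4.27-fold higher at pH 6, with 70.9 ± 12.1 against 13.99 ± 5.32. The genes highest at pH 4.5 included EXLA2 (AT4G38400), an expansin-like gene, at 275 ± 26.2 against 17.3 ± 3.18 at pH 6, and EXO (AT4G08950), the brassinosteroid-responsive EXORDIUM gene, at 2664 ± 376 against 206 ± 27.3. Their log2 differences, pH 6 minus pH 4.5, were -3.73 ± 0.22 (adjusted p = 1.12e-09) and -3.67 ± 0.12 (adjusted p = 2.59e-13). AT5G52760, which encodes a protein with a heavy-metal-associated domain, had a signal of 118 ± 18.9 at pH 4.5 and 2.202 ± 2.66 at pH 6. That lower mean lies under the signal level of 10.4 that the filter on low probe sets corresponds to, so its log2 difference of -4.38 ± 0.26 understates the ratio of the signals.

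After 1 h, the other named genes with the largest differences on the higher side at pH 6 were AT2G36690, a 2-oxoglutarate-dependent oxygenase (5.47-fold), AT1G33840 (4.302-fold), AT3G59850, a pectin lyase-like protein (3.502-fold), CCL (AT3G26740, 3.35-fold) and AT1G14260 (3.09-fold). AT1G30700, AT1G26420 and AT1G26380, berberine-bridge-enzyme-like oxidoreductases, were 3.75-fold, 3.85-fold and 3.39-fold higher at pH 6. At pH 4.5 the higher genes included EXLA1 (AT3G45970; 5.07-fold) and EXLA3 (AT3G45960; 4.99-fold), which are also expansin-like. AT5G66650, a member of the mitochondrial calcium uniporter family, was 8.72-fold higher at pH 4.5, and AT4G27280, a calcium-binding EF-hand protein, was 6.98-fold higher. The remaining 3 were AT1G59660 (6.07-fold), GAT1_2.1 (AT1G15040; 5.59-fold), a glutamine amidotransferase-like gene with a wide spread (257 ± 40.9 against 49.4 ± 32.4), and AT4G37240 (4.84-fold). The lower means of AT3G59850 (8.76) and AT1G26420 (7.27) were also under the low-signal level.

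**Figure D1:**
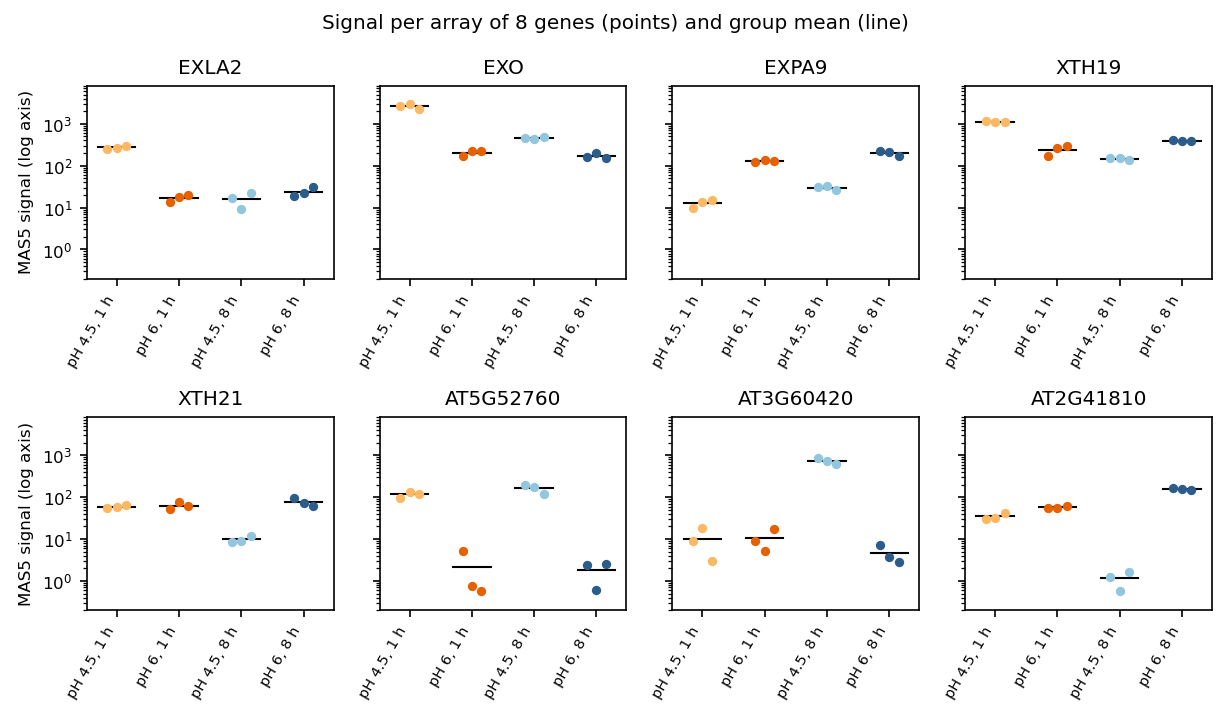
Array signals (log axis, trimmed mean 100 per array) of 8 named genes in the 4 groups, with 1 point per array and a bar at the mean of 3. EXLA2 stood at 275 in the pH 4.5, 1 h group and at 16.1 to 24.1 in the other groups, and AT3G60420 stood at 734 in the pH 4.5, 8 h group and at 4.57 to 10.6 in the other groups.

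Of the 5 fixed gene lists that could be tested, 4 were shifted relative to the other genes at 1 h by camera, limma's competitive test, and all 4 were lower at pH 6. Of 6 measured calcium and touch genes, which encode calmodulin-like proteins, 4 were lower and 0 higher (also 4 and 0 adjusted over the list alone), with a median log2 difference of -1.36 (adjusted p = 9.29e-07). They included CML38 (-2.11), AT1G76640 (-2.09) and CML37 (-1.60). Of 8 xyloglucan endotransglucosylase/hydrolase (XTH) genes, which remodel wall xyloglucan, 4 were lower and 1 higher (5 and 1 adjusted over the list alone), with a median of -0.42 (adjusted p = 0.000373). XTH19 (AT4G30290; -2.23) and XTH18 (AT4G30280; -1.95) led this list. Of 6 class III peroxidases, 3 were lower and 0 higher (3 and 0 adjusted over the list alone; median -0.27, adjusted p = 0.00248). Of 7 auxin response genes, 1 was lower and 0 higher (1 and 1 adjusted over the list alone; median -0.24, adjusted p = 0.0173), and the 1 was GH3.1 (AT2G14960; -1.94), which encodes an auxin-conjugating enzyme. The call of the auxin list was lost without the filter on low probe sets (adjusted p = 0.0777). With an estimated correlation between genes, the adjusted p was 0.00345 for the calcium and touch list and 0.0456 for each of the others, so all 4 calls held.

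The expansin list divided at 1 h. EXPB1 was higher at pH 6, and the 3 expansin-like genes EXLA1, EXLA2 and EXLA3 were lower, with 6 of 10 members not past the test. EXPA9, higher at pH 6, is not in this fixed list, so the counts and the averages leave it out. Adjusted over the list alone, 3 were higher and 3 lower, EXPA7 and EXPA15 (0.37 each) being the further 2. The median was 0.17, while the mean was -0.49 and the test pointed down (adjusted p = 0.275).

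Among the lists added later, pectate lyases, which cleave pectin, had 7 of 11 measured members higher at pH 6 after 1 h and 0 lower, with a median of 0.38 (adjusted p = 2.37e-06, and adjusted p = 0.0194 with an estimated correlation). AT3G07010 (1.18) and AT1G67750 (1.11) had the largest differences. Of 20 early stress genes, which respond quickly to wounding or elicitors, 12 were lower and 5 higher at pH 6 (median -0.63, adjusted p = 0.000410, and adjusted p = 0.382 with an estimated correlation). AT5G64870 (-2.08) and STZ (AT1G27730, -1.35), a zinc-finger transcription factor, were lower at pH 6, while WRKY53 (AT4G23810, 1.15) and WRKY22 (AT4G01250, 0.78) were higher. CML37 and CML38 belong to this list and to the calcium and touch list. Of 19 pectin methylesterase family genes, 4 were lower and 0 higher (median -0.06, adjusted p = 0.0151, and adjusted p = 0.418 with an estimated correlation), and the 4 included ATPMEPCRB (AT4G02330; -1.95) and AT1G02810 (-1.84). Of 43 plastid-encoded photosynthesis genes, 5 were higher and 0 lower (median 0.21, adjusted p = 0.0412, and adjusted p = 0.712 with an estimated correlation). Single arrays decided these last 2 calls. The pectin methylesterase call ended without replicate 2 of pH 4.5 (adjusted p = 0.0530) or replicate 1 of pH 6 (adjusted p = 0.0853), and the plastid call without replicate 2 of pH 6 (adjusted p = 0.422) or replicates 2 or 3 of pH 4.5 (adjusted p = 0.105 and 0.0639).

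In all, 1706 of 15922 probe sets (10.7%) differed between pH 6 and pH 4.5 at 1 h by limma's moderated test at an adjusted p of 0.05. Of these, 829 were higher and 877 lower at pH 6, and 311 differed at least 2-fold, 99 of them higher and 212 lower. The share of higher calls was 48.6%, and 33.7% when each array was centred on its median. Median signals were 40.1 ± 0.182 in the pH 6, 1 h group and 38.2 ± 0.0589 in the pH 4.5, 1 h group. Hybridisation spike-in signals averaged 241 ± 13.0 and 331 ± 114 in these groups, and 3' to 5' signal ratios of actin averaged 14.6 ± 4.02 and 19.9 ± 1.51. The same ratios averaged 1.11 ± 0.169 and 1.37 ± 0.111 for GAPDH, and 2.27 ± 0.0836 and 2.25 ± 0.222 for ubiquitin. Median signals and actin ratios did not overlap between these groups, so their influence cannot be told apart from that of pH.

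After 8 h, early stress genes, calcium and touch genes and class III peroxidases were lower at pH 6, while pectate lyases were higher. AT2G41810, which encodes a wall protein of the DUF642 family, had a signal of 158 ± 11.3 at pH 6 and 1.15 ± 0.55 at pH 4.5 (log2 difference 5.00 ± 0.16, adjusted p = 1.01e-13). AT4G25250, a pectin methylesterase inhibitor, stood at 265 ± 30.7 against 7.44 ± 1.02 (4.57 ± 0.16, adjusted p = 3.33e-13), and AT3G19430 at 500 ± 8.10 against 31.1 ± 0.947 (3.85 ± 0.14). AT3G60420, a phosphoglycerate mutase family gene, had a signal of 734 ± 108 at pH 4.5 and 4.57 ± 2.36 at pH 6 (-6.47 ± 0.34, adjusted p = 6.25e-11). AT2G41380, a methyltransferase, stood at 301 ± 15.3 against 5.29 ± 2.03 (-5.07 ± 0.18), and ICL (AT3G21720), isocitrate lyase of the glyoxylate cycle, at 149 ± 15.8 against 7.20 ± 2.22 (-3.80 ± 0.34, adjusted p = 9.91e-08). AT5G52760 was again higher at pH 4.5, with 162 ± 36.5 against 1.85 ± 1.09. In AT2G41810, AT4G25250, AT3G60420, AT2G41380, ICL and AT5G52760 the lower mean was under the level of the low-signal filter, where the added constant reduces the log2 difference.

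The other named genes with the largest differences on the higher side at pH 6 after 8 h were AT1G09750, an aspartyl protease (13.7-fold), AT4G22460, a lipid-transfer-type protein (13.2-fold), AT3G59370 (9.47-fold), sks15 (AT4G37160), a relative of SKU5 (7.98-fold), AT5G66815, which encodes a CEP-type signal peptide (7.15-fold), AT2G43880, a polygalacturonase (7.00-fold), and AT1G50050, of the pathogenesis-related CAP family (6.94-fold). At pH 4.5 the higher genes were AT3G47480, an EF-hand protein (20.3-fold), AT3G28580, an AAA-type ATPase (12.5-fold), AT5G52670, a second gene with a heavy-metal-associated domain (12.1-fold), AT1G19020 (11.9-fold), AT3G16530, a lectin-type protein (11.2-fold), and AT1G72900, a TIR-domain protein (11.0-fold). Among these 13 genes the lower mean was under the low-signal level in AT1G09750 (9.45), AT5G66815 (3.68), AT2G43880 (8.65), AT3G47480 (7.33), AT3G28580 (2.24), AT3G16530 (8.08) and AT1G72900 (5.26).

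The calcium and touch list was lower at pH 6 at 8 h as well. Of its 6 members, 5 were lower and 0 higher (also 5 and 0 adjusted over the list alone, median -1.69, adjusted p = 7.26e-05), with CML37 (-2.46), CML41 (-2.42) and CML38 (-2.01) lowest. At pH 6 and 8 h the signals of CML37 were 1.75, 0.33 and 0.38, under the low-signal level. The class III peroxidases had 5 of 6 members lower and 0 higher (5 and 1 adjusted over the list alone; median -1.18, adjusted p = 4.41e-05), led by AT5G39580 (-2.83) and AT5G64120 (-1.63). The auxin response list had 4 of 7 members lower and 0 higher (4 and 0 adjusted over the list alone; median -0.52, adjusted p = 0.00404). Among them were LBD29 (AT3G58190; -1.35) and LBD16 (AT2G42430; -1.31), transcription factors of lateral root initiation. With an estimated correlation these 3 calls held, at adjusted p = 0.0133, adjusted p = 0.0137 and adjusted p = 0.0284. The XTH list, lower at pH 6 at 1 h, was higher at pH 6 at 8 h, with 5 of 8 members higher and 2 lower (5 and 2 adjusted over the list alone, median 0.99, adjusted p = 0.00285, and adjusted p = 0.0816 with an estimated correlation). XTH21 (AT2G18800, 2.52), XTH16 (AT3G23730, 2.47) and XTH19 (1.40) were higher at pH 6, and XTH26 (AT4G28850, -1.57) was lower. Of the 10 expansins, 4 were higher and 2 lower (5 and 2 adjusted over the list alone; median 0.39, adjusted p = 0.114), with EXPB1 at 2.25 and EXLB1 (AT4G17030) at -1.47.

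**Figure D2:**
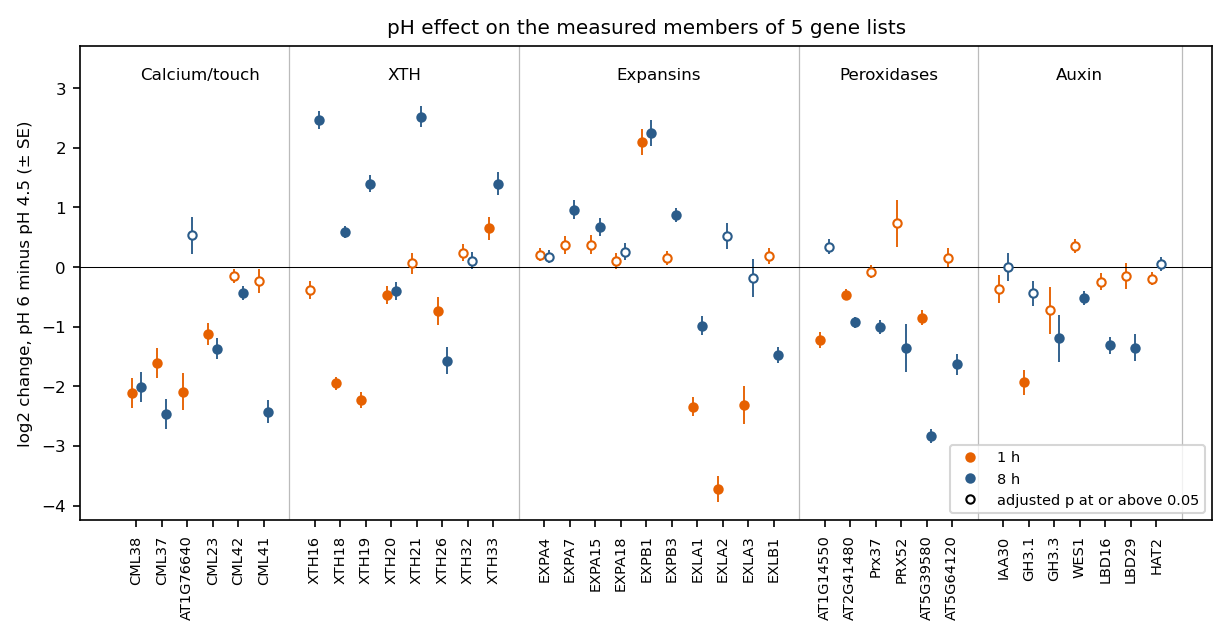
Log2 difference between pH 6 and pH 4.5 (vertical axis, ± SE of limma's fit) for the 37 measured members of 5 gene lists, at 1 h and at 8 h. All 4 calcium and touch genes that passed the test at 1 h lay below 0, while XTH18 and XTH19 moved from -1.95 and -2.23 at 1 h to 0.59 and 1.40 at 8 h.

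At 8 h, 10 of the 28 added lists tested were shifted relative to the other genes, and 4 of these calls held with an estimated correlation. The early stress genes had 15 of 20 members lower at pH 6 and 1 higher (median -1.31, adjusted p = 3.30e-12, and adjusted p = 0.0235 with an estimated correlation), with AT1G19020 (-3.57), AT2G22880 (-3.35) and STZ (-1.62) among the lower. The wider class III peroxidase family, which contains the 6 genes above, had 23 of 42 members lower and 9 higher (median -0.50, adjusted p = 0.000778, and adjusted p = 0.0235 with an estimated correlation). Its lowest members were AT5G39580 (-2.83) and AT1G49570 (-1.86), and its highest was AT2G39040 (2.70). Pectate lyases had 8 of 11 members higher and 0 lower (median 0.64, adjusted p = 3.45e-05, and adjusted p = 0.0235 with an estimated correlation), among them AT3G07010 (1.60) and AT5G48900 (1.05). UDP-glycosyltransferases, which attach sugars to small molecules, had 10 of 27 members lower and 2 higher (median -0.20, adjusted p = 0.00223, and adjusted p = 0.0404 with an estimated correlation), led by UGT73D1 (AT3G53150; -3.19) and UGT87A2 (AT2G30140; -1.91).

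The other 6 added lists passed only with the preset correlation. Cytosolic ribosomal proteins had 39 of 56 members higher at pH 6 after 8 h and 1 lower (median 0.39, adjusted p = 1.34e-11, and adjusted p = 0.244 with an estimated correlation). Autophagy genes had 7 of 10 members lower and 0 higher (median -0.44, adjusted p = 0.000146, and adjusted p = 0.244 with an estimated correlation), including ATG8B (AT4G04620; -0.90) and ATG8D (AT2G05630; -0.70). Trichome birefringence-like genes, whose products acetylate wall polymers, had 7 of 17 members higher and 0 lower (median 0.32, adjusted p = 0.00195, and adjusted p = 0.235 with an estimated correlation), including TBL39 (1.25) and TBL25 (1.00). GH9 endoglucanases had 3 of 7 members higher and 0 lower (median 0.33, adjusted p = 0.0222, and adjusted p = 0.235 with an estimated correlation). Mitosis genes had 6 of 16 members higher and 0 lower (median 0.36, adjusted p = 0.0176, and adjusted p = 0.164 with an estimated correlation). Of 8 CYP71B cytochrome P450 genes, 2 were lower and 0 higher (median -0.22, adjusted p = 0.0453, and adjusted p = 0.293 with an estimated correlation). The CYP71B call also ended without replicate 2 of pH 4.5 (adjusted p = 0.113) or replicates 1 or 3 of pH 6 (adjusted p = 0.0520 and 0.0996).

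At 8 h, 4416 probe sets (27.7%) differed with pH, 2312 of them higher and 2104 lower at pH 6, and 923 differed at least 2-fold (341 higher, 582 lower). Of the 8664 named genes tested, 2267 differed at 8 h and 874 at 1 h.

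The pH effects at the 2 times overlapped in part. Across the 15922 probe sets the log2 differences at 1 h and at 8 h, which come from separate arrays, correlated at r = 0.301. Of 932 probe sets called at both times, 296 were higher and 414 lower at pH 6 at both, and 222 had opposite directions. Independent calls would give 120, 116 and 237. All calls used 1 estimate of spread per probe set, so they are not independent and these expected numbers may be too low. AT5G52760, CML38 and CML37 were lower at pH 6 at both times, and EXPA9 and EXPB1 were higher at both.

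The difference between the pH effects was tested directly and passed in 2455 probe sets (15.4%), with 1139 effects higher at 8 h and 1316 lower. The share of higher differences was 46.4%, and 56.7% when each array was centred on its median. EXLA2 differed between the pH values at 1 h (-3.73) and had a value of 0.52 ± 0.22 at 8 h that did not pass the test, a difference of 4.24 ± 0.30 (adjusted p = 1.57e-08). XTH19 went from -2.23 at 1 h to 1.40 at 8 h (difference 3.63 ± 0.20, adjusted p = 4.32e-10). Among the named genes, these 2 and AT2G41810 (4.33), AT3G19430 (3.93), AT4G25250 (3.595) and AT4G22460 (3.44) had the largest differences on the pH 6 side, and AT3G60420 (-6.59), AT2G41380 (-4.05), AT3G47480 (-3.75), ICL (-3.74) and AT3G13950 (-3.67) were among the largest on the pH 4.5 side. Probe sets that name no single gene reached 5.20. AT1G26420 was higher at pH 6 at 1 h (1.94) and higher at pH 4.5 at 8 h (-1.64), a difference of -3.58 ± 0.31 (adjusted p = 1.60e-07).

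Among the fixed lists, the mean difference between the pH effects was 1.41 for the XTH genes (4 of 8 members higher and 0 lower, and 5 and 1 adjusted over the list alone, adjusted p = 4.22e-06, and adjusted p = 0.0501 with an estimated correlation). For the expansins it was 0.80 (4 higher and 1 lower, and 5 and 1 adjusted over the list alone, adjusted p = 0.00476, and adjusted p = 0.0771 with an estimated correlation). The class III peroxidases gave -0.95 (1 higher and 5 lower, also 1 and 5 adjusted over the list alone, adjusted p = 0.00265, and adjusted p = 0.0603 with an estimated correlation). The calcium and touch list (-0.14, 1 higher and 1 lower, adjusted p = 0.332) and the auxin list (-0.21, 1 higher and 3 lower, adjusted p = 0.332) did not pass, with the same counts adjusted over the list alone.

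**Figure D3:**
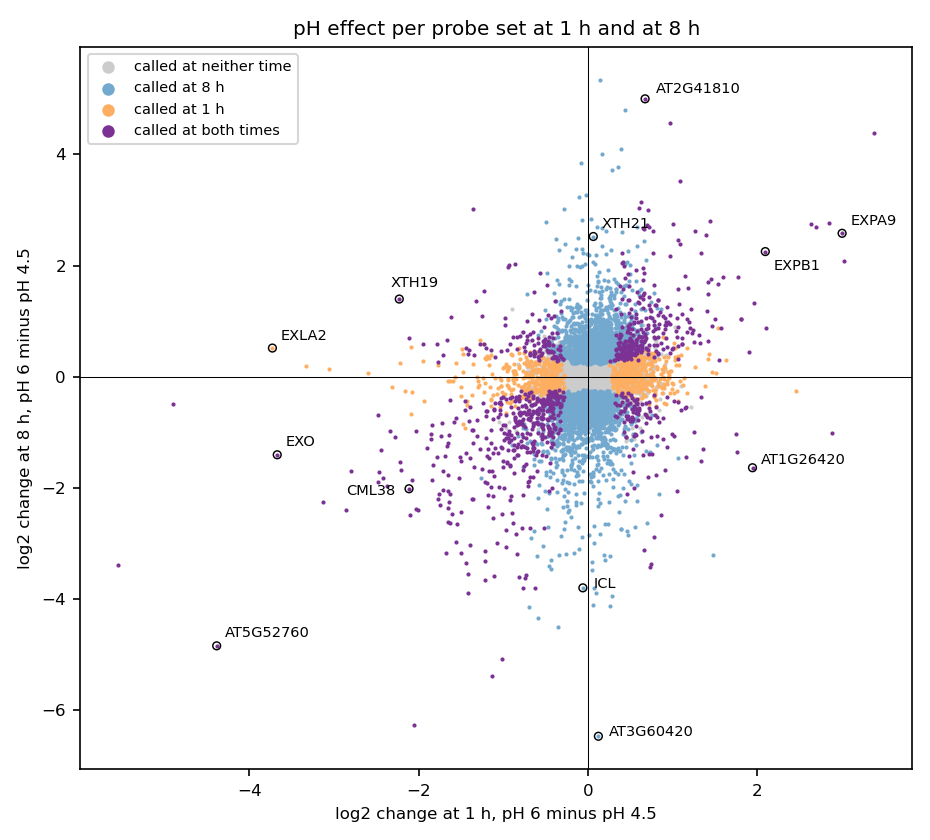
Log2 difference between pH 6 and pH 4.5 at 1 h (horizontal axis) and at 8 h (vertical axis) for the 15922 probe sets, coloured by the times at which they were called, with named genes marked. The correlation was 0.301, and EXLA2 (-3.73 at 1 h) and AT3G60420 (-6.47 at 8 h) lay far along a single axis.

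At pH 4.5, XTH genes fell between 1 h and 8 h, and AT3G60420 and ICL had the largest increases of the named genes. AT3G60420 went from 10.0 ± 7.59 to 734 ± 108 (log2 difference 5.87 ± 0.34, adjusted p = 3.47e-10) and ICL from 4.37 ± 5.32 to 149 ± 15.8 (4.38 ± 0.34, adjusted p = 2.15e-08), both from means below the low-signal level. AT2G41380 (9.84-fold), AT3G47480 (8.86-fold), AT3G28510, an AAA-type ATPase (8.42-fold), and AT2G23910 (7.26-fold) also rose. EXLA2 fell 14.4-fold, AT1G76640, a calmodulin-like gene, 13.7-fold, AT1G09750 12.6-fold, AT4G22460 10.8-fold, AT3G19430 8.85-fold and XTH16 7.95-fold. The 8 h means of AT1G76640 (2.13) and AT1G09750 (9.45) were under the low-signal level. The XTH list fell, with 4 of 8 members lower and 0 higher at 8 h (5 and 0 adjusted over the list alone; median -1.37, adjusted p = 4.59e-07, and adjusted p = 0.0330 with an estimated correlation). The class III peroxidases had 4 of 6 members higher and 1 lower (4 and 1 adjusted over the list alone; median 0.87, adjusted p = 0.0417, and adjusted p = 0.193 with an estimated correlation). Leaving out replicate 2 at 1 h (adjusted p = 0.0695) or replicate 3 at 8 h (adjusted p = 0.0600) ended that call. The auxin, calcium and touch, and expansin lists did not pass (adjusted p = 0.262 each). They had 2 of 7, 1 of 6 and 4 of 10 members higher and 1, 2 and 4 lower, the same counts adjusted over the list alone. The expansin median was -0.11 and its mean -0.50.

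Of the 28 added lists, 5 passed in this comparison, 0 of them with an estimated correlation. UDP-glycosyltransferases had 11 of 27 members higher at 8 h and 1 lower (median 0.24, adjusted p = 0.00209, and adjusted p = 0.0626 with an estimated correlation), and UGT87A2 rose by 1.65. Unfolded protein response genes had 3 of 13 members higher and 0 lower (median 0.22, adjusted p = 0.0471, and adjusted p = 0.165 with an estimated correlation), a call that also ended without replicates 1 or 3 at 1 h (adjusted p = 0.0637 and 0.0606) or replicates 1 or 2 at 8 h (adjusted p = 0.0705 and 0.0583). Pectin methylesterase family genes had 9 of 19 members lower and 0 higher (median -0.44, adjusted p = 0.00168, and adjusted p = 0.176 with an estimated correlation). Nuclear photosynthesis genes had 7 of 10 members lower and 0 higher (median -0.94, adjusted p = 0.000175, and adjusted p = 0.0626 with an estimated correlation), including RCA (AT2G39730; -1.02) and LHCB4.1 (AT5G01530; -0.91). Cytosolic ribosomal proteins had 5 of 56 members lower and 1 higher (median -0.16, adjusted p = 0.000175, and adjusted p = 0.541 with an estimated correlation). In total 3761 probe sets (23.62%) differed between 8 h and 1 h at pH 4.5, 1997 higher and 1764 lower at 8 h, and 768 differed at least 2-fold. The larger side depended on the scaling, with 1763 higher and 1941 lower when each array was centred on its median. The array signal of 25S ribosomal RNA was 1399 ± 298 at 1 h and 2151 ± 317 at 8 h in these groups, and the median signals were 38.2 ± 0.0589 and 39.1 ± 0.826, both without overlap.

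At pH 6, early stress genes fell between 1 h and 8 h by the test with the preset correlation and not with an estimated one (adjusted p = 0.0532), and the largest increase of a named gene was 4.72-fold. AT4G10270, of a wound-responsive family, went from 24.2 ± 3.44 to 130 ± 26.3 (4.72-fold, adjusted p = 6.30e-07), and AT4G33560, of the same family, rose 3.93-fold from 9.72 ± 3.65, just under the low-signal level. AT3G10040, the hypoxia-responsive HRA1 gene, rose 3.85-fold, COR27 (AT5G42900), a cold-regulated clock-associated gene, 3.5-fold, AT2G48080 3.93-fold and AT2G23910 3.45-fold. AT3G16800, a protein phosphatase 2C, fell from 322 ± 13.4 to 55.8 ± 4.34 (log2 difference -2.45 ± 0.10, adjusted p = 1.95e-11). AT5G59540 fell 5.46-fold, PSAN (AT5G64040), a photosystem I subunit, 5.07-fold, AT1G26420 4.81-fold, AT1G19020 4.76-fold and AR781 (AT2G26530) 4.74-fold. The 1 h mean of COR27 (6.91) and the 8 h means of AT5G59540 (1.01), PSAN (6.11) and AT1G26420 (5.24) were under the low-signal level.

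Of the 5 fixed lists, 0 passed at pH 6 by camera, where 3094 probe sets differed by limma's test and 5121 had an unadjusted p under 0.05. The lowest adjusted p was 0.0505, for the calcium and touch genes (0 of 6 higher, 4 lower, median -0.78; also 0 and 4 adjusted over the list alone). With a replicate block, without the filter or with the spike-in covariate 2 lists passed, the calcium and touch genes (lower) and the expansins (higher), and over all alternatives their adjusted p ranged from 0.000951 to 0.149 and from 0.0183 to 0.323. Both also passed without replicate 2 at 1 h (adjusted p = 0.0256 each) or replicate 2 at 8 h (adjusted p = 0.0137 and 0.0407), and the calcium and touch genes without replicate 3 at 1 h (adjusted p = 0.0400). By fry, which tests whether genes of a list move one way and does not compare them with other genes, 3 lists passed. The expansins had 3 of 10 members higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.0780). XTH genes had 1 of 8 higher and 0 lower, auxin genes 1 of 7 higher and 1 lower, and class III peroxidases 1 of 6 higher and 2 lower, each the same adjusted over the list alone (adjusted p = 0.707, 0.789 and 0.229).

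At pH 6, 10 added lists passed, and 0 of them with an estimated correlation. Early stress genes had 17 of 20 members lower at 8 h and 0 higher (median -0.83, adjusted p = 2.00e-13, and adjusted p = 0.0532 with an estimated correlation), including AT1G19020 (-2.25) and STZ (-1.24). Cytosolic ribosomal proteins had 15 of 56 members higher and 0 lower (median 0.23, adjusted p = 8.86e-08, and adjusted p = 0.307 with an estimated correlation). Quantile normalization ended that call as well (adjusted p = 0.109). Nuclear photosynthesis genes had 5 of 10 members lower (median -0.57, and adjusted p = 0.106 with an estimated correlation), autophagy genes 3 of 10 (median -0.28, and adjusted p = 0.331 with an estimated correlation) and CYP71B genes 2 of 8 (median -0.33, and adjusted p = 0.264 with an estimated correlation), with 0 higher in each. Chaperones (3 of 7 higher, median 0.25), GH9 endoglucanases (3 of 7, 0.41), RALF signal peptides (2 of 6, 0.37) and pectate lyases (2 of 11, 0.25) had 0 members lower, each with adjusted p = 0.193 with an estimated correlation. Trichome birefringence-like genes had 2 of 17 higher and 0 lower (median 0.19, and adjusted p = 0.309 with an estimated correlation). Leaving out replicate 1 at 1 h ended the calls of the trichome birefringence-like (adjusted p = 0.114), GH9 and RALF lists (adjusted p = 0.0639 each). Leaving out replicate 2 at 8 h ended the trichome birefringence-like (adjusted p = 0.127) and RALF calls (adjusted p = 0.0677), and replicate 3 at 8 h the autophagy and CYP71B calls (adjusted p = 0.0648 each). Without replicate 2 at 1 h the CYP71B call ended (adjusted p = 0.0818), and without replicate 3 at 1 h or replicate 1 at 8 h the trichome birefringence-like call (adjusted p = 0.0667 and 0.0509).

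**Figure D4:**
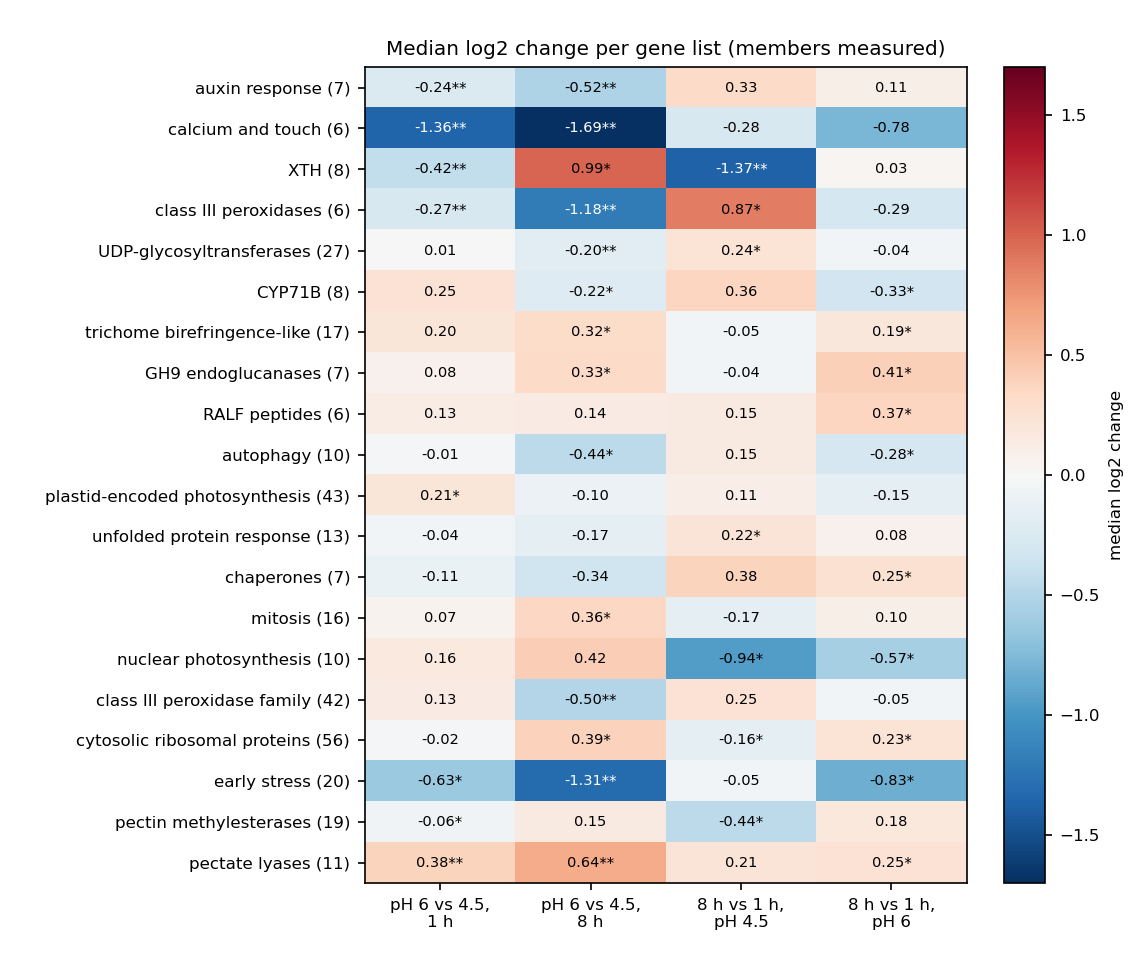
Median log2 change (colour and number) of 20 gene lists in 4 comparisons, with the number of measured members beside each name; 1 asterisk marks a list past an adjusted p of 0.05 by camera and 2 asterisks a list that also passed with an estimated correlation. The calcium and touch genes were lowest, at -1.36 and -1.69 in the pH comparisons, and the XTH genes went from -0.42 at 1 h to 0.99 at 8 h.

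Of the 3094 probe sets (19.4%) that differed between the times at pH 6, 1411 were higher and 1683 lower at 8 h, and 423 differed at least 2-fold (101 higher, 322 lower). Here too the larger side depended on the scaling, with 1709 higher and 1483 lower when each array was centred on its median. The median signals of these groups did not overlap either (40.1 ± 0.182 at 1 h and 39.1 ± 0.656 at 8 h), while those of 25S ribosomal RNA did (1638 ± 307 and 2042 ± 757). Across probe sets, the time effects at the 2 pH values correlated at r = 0.207. In both comparisons 1443 probe sets were called, 460 higher at 8 h at both pH values (177 by chance), 539 lower at both (186 by chance) and 444 in opposite directions (367 by chance).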

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

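The tests of the XTH genes, of the nuclear photosynthesis genes and of the number of probe sets at the 2 times, and the exchange of residuals, were chosen only after those results were seen, and the counts over other splits of the arrays were planned.

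The pH effect differed between 1 h and 8 h in 2455 probe sets (15.4%) by limma's test of the difference, and in 1243 of all 8664 named genes tested. It differed in 129 of the 216 genes named by the rule, which were chosen for large differences in the same data. Among the 216, 48 were called in the same direction at both times and 12 in opposite directions. The differences below are the effect at 8 h minus that at 1 h, on the log2 scale, and each was past an adjusted p of 0.05. They were 4.33 for AT2G41810, 4.24 for EXLA2, 3.93 for AT3G19430, 3.63 for XTH19, 3.595 for AT4G25250, 3.44 for AT4G22460 and 2.54 for XTH18. On the other side they were -6.59 for AT3G60420, -4.05 for AT2G41380, -3.75 for AT3G47480, -3.74 for ICL, -3.67 for AT3G13950 and -3.58 for AT1G26420. Genes called in opposite directions at the 2 times also had differences of -3.11 (AT1G26380), -2.78 (CCL), 0.96 (HTB1), -1.47 (AT1G44970), 0.97 (AT3G10720), -1.17 (CYP71B29), 1.796 (GH9C3) and -1.91 (AT5G12340). HTB1 encodes a histone H2B, AT1G44970 a class III peroxidase, AT3G10720 a pectin methylesterase and GH9C3 an endoglucanase. The call of CYP71B29 at 8 h ended without replicates 1 or 3 of pH 4.5 (adjusted p = 0.0619 and 0.0928) or replicates 1 or 2 of pH 6 (adjusted p = 0.0943 and 0.0567).

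The mean difference between the pH effects passed the test with the preset correlation in 14 lists, and in 0 of them with an estimated correlation, where adjusted p was 0.0501 or more. Higher at 8 h than at 1 h were expansins (0.80), XTH genes (1.41), trichome birefringence-like genes (0.26), GH9 endoglucanases (0.53), mitosis genes (0.28), cytosolic ribosomal proteins (0.38) and pectin methylesterase family genes (0.52). Their medians, in this order, were 0.45, 1.60, 0.18, 0.25, 0.25, 0.39 and 0.18. Lower were class III peroxidases (-0.95) and their wider family (-0.41), UDP-glycosyltransferases (-0.44), CYP71B genes (-0.54), autophagy genes (-0.48), plastid-encoded photosynthesis genes (-0.35) and early stress genes (-0.76). The medians of these lists, in this order, were -1.36, -0.48, -0.31, -0.61, -0.49, -0.31 and -0.66. Leaving out replicate 1 of pH 6 at 1 h ended the trichome birefringence-like and GH9 calls (adjusted p = 0.0578 each), replicate 2 of pH 6 at 8 h the trichome birefringence-like call (adjusted p = 0.0684) and replicate 2 of pH 6 at 1 h the plastid call (adjusted p = 0.0714).

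For the count of probe sets whose pH effect differed, splits that exchange pH labels within each time remove the pH effects themselves and so do not test whether the effects are equal. Of 100 such splits drawn, 2 gave a count as high as 2455, the real one included, and the highest other counts were 4163 and 2296. The 4163 came from exchanging all labels at 1 time, which tests the sum of the pH effects. In a test chosen later, the residuals of a model with a pH effect and a time effect were exchanged between the 12 arrays. Of 100 such exchanges 1, the real one, gave a count as high as 2455, and the highest other count was 1. Chance can be excluded at 0.05 as the source of the whole count only if the 12 arrays are independent samples. The labels do not say whether replicates came from separate cultures, so chance differences between cultures stay open. For the pH and time comparisons, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The counts as high were 1 of 10 in each (the real split). The pH comparisons had 1706 against at most 1 at 1 h and 4416 against at most 0 at 8 h. The time comparisons had 3761 against at most 0 at pH 4.5 and 3094 against at most 1 at pH 6. Mixed splits carry any difference between the groups into the spread, which lowers their counts, so these gaps add no support. For the fixed lists the real counts were 4, 4, 2 and 0, against at most 3, 2, 1 and 3 in other splits, so lists were called in splits that mix the groups. A count as high came in 1 split in the first 3. At pH 6 the real count of 0 makes all 10 of 10 splits as high by construction, so nothing was tested there.

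Of 8 XTH genes, 4 were lower and 1 higher at pH 6 at 1 h, and 5 were higher and 2 lower at 8 h, where the list call was lost with an estimated correlation (adjusted p = 0.0816). Array scaling is argued against by its small size. The median difference over all probe sets was -0.021 as deposited, 0.011 under quantile normalization and 0.041 under median centring. The list's mean difference was 1.41 as deposited, and the lower of its values under these scalings was 1.44. Shifts so small could hardly have removed it, so that last value adds little. A single deviating array is argued against by an adjusted p of at most 1.62e-05 over the 12 fits without 1 array. Those fits used the preset correlation and were not repeated with an estimated one. Cross-hybridisation between similar genes stays open. Of the 8 measured members 0 are read by a probe set that the array design marks as shared, but members were measured only through probe sets that the annotation gives to 1 gene, so this excludes nothing. A pH effect on XTH genes that changes with time stays open beside it, and its list call had an adjusted p of 0.0501 with an estimated correlation.

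Of 10 measured nuclear photosynthesis genes, 7 were lower at 8 h than at 1 h at pH 4.5 (median -0.94) and 5 at pH 6 (median -0.57), and both list calls were lost with an estimated correlation (adjusted p = 0.0626 and 0.106). More shoot tissue in the 1 h samples could lower plastid-encoded transcripts at 8 h too. Over 43 such genes the median was 0.11 (SE 0.035) at pH 4.5 and -0.15 (SE 0.066) at pH 6. These SEs came from resampling genes, which are not independent, and do not measure the spread between arrays. By camera the list passed at neither pH (adjusted p = 0.214 at pH 4.5 and 0.0568 at pH 6). No shoot sample was analysed here, so how much of the plastid signal comes from root plastids is unknown and shoot tissue stays open. At 1 h the mean signals were 52.1 for RCA, 69.6 for LHCB4.1, 93.8 for rbcL and 59.0 for psbB. The sampling times were 7 h apart and the labels give no clock time, so time of day and hours of treatment cannot be told apart in these genes.

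More probe sets differed with pH at 8 h than at 1 h, by a ratio of 2.59. With the spike-in signal as a covariate the ratio was 2.97. Of the reported calls, 1299 of 1706 at 1 h and 4012 of 4416 at 8 h were kept. The signal averaged 331 at pH 4.5 and 241 at pH 6 at 1 h, and 401 and 346 at 8 h. It was thus more tied to pH at 1 h, where the covariate took a larger share of calls. The higher ratio therefore does not decide on array quality. The 3' to 5' signal ratios were not tested in this way. Unequal spread of the arrays at the 2 times is argued against, with a ratio of 2.82 when each comparison was fitted on its own 6 arrays. Array quality stays open. The duration of the treatment and the hour of sampling remain open as well and were not separated by the design.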

How the results depend on the processing

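The spike-in covariate and the omission of arrays by their spike-in signals were chosen after the data were seen; the other alternatives were planned. Under all alternatives the counts of probe sets stayed within 1.5 times the reported ones. Of 352 results for single genes 287 kept their direction and side of the threshold throughout, and 0 reversed. These genes were chosen because they were past the threshold in the same data, so their calls could only be lost and a reversal was unlikely. Over these results, calls were lost 201 times with 1 array left out and 172 times under the other settings. Of 165 results for lists 79 were kept throughout and 0 reversed. List calls were lost 28 times and gained 21 times with 1 array left out, and lost 78 times and gained 70 times under the other settings. Of these, 40 of the losses came with an estimated correlation and 44 of the gains by fry, which does not compare a list with other genes. Without 1 array, the counts were 1220 to 1491 (pH, 1 h), 3546 to 3904 (pH, 8 h), 2018 to 2436 (difference), 2851 to 3283 (time, pH 4.5) and 2248 to 2771 (time, pH 6), and the correlation of the pH effects was 0.256 to 0.337. It was 0.236 with no filter (reported 0.301, jackknife SE 0.0618). Without replicate 3 of pH 4.5 at 1 h and replicate 1 of pH 6 at 8 h the counts were 1379, 3910, 2065, 3140 and 2686 in that order, with replicate 2 left out in place of that replicate 1 they were 1486, 3853, 1872, 3253 and 2445, and with the covariate 1424, 4230, 2546, 3515 and 2617. No scaling moved the median of all probe sets by over 0.1 (log2).

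The numbers of fixed lists called moved more. At pH 4.5 over time, 2 lists were reported. There was 1 with a constant of 1% (4 lists tested), a filter at the 50th percentile (3 tested), eBayes without trend or an estimated correlation, and there were 4 by fry. At pH 6 over time 0 were reported, and there were 2 with no filter (6 tested), a replicate block, the spike-in covariate or without replicate 3 of pH 4.5 at 1 h and replicate 2 of pH 6 at 8 h together, 1 with median centring, array weights or only unique probe sets, and 3 by fry. The filter at the 50th percentile left 2 called for pH at 1 h and 2 at 8 h, where fewer lists were tested. Without 1 array the counts were 4 in both pH comparisons, 1 to 2 at pH 4.5 (1 without replicate 2 at 1 h or replicate 3 at 8 h) and 0 to 2 at pH 6 (2 without replicate 2 at 1 h or at 8 h, 1 without replicate 3 at 1 h). Beyond the number of lists tested, the cause was not tested. With the replicate block the probe set counts were 1839, 4582, 2610, 3875 and 3239. Deviations of arrays with the same replicate number correlated at -0.037 to 0.138 for pH at 1 h and 0.050 to 0.110 at 8 h. Arrays closest to their own number were 3 of 6 at 1 h and 6 of 6 at 8 h. Over time they were 1 of 6 at pH 4.5 and 4 of 6 at pH 6. The numbers thus did not consistently pair the samples, but a factor shared by equal numbers is not excluded. Fits on only the arrays compared were run for the probe sets and not for the lists. Signal over background limits genes with means under 10.4.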

Other observations

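At 8 h AT5G51490, a pectin methylesterase family gene, was higher at pH 6 by 2.63 ± 0.25 (log2, SE, n = 3 arrays per group, limma adjusted p = 2.34e-07), and AT5G04970 of the same family by 1.67. At 1 h neither passed the test (0.21, adjusted p = 0.676, and 0.35, adjusted p = 0.165). The family as a whole had 5 of 19 members higher and 1 lower at 8 h (median 0.15, adjusted p = 0.197), and 4 lower and 0 higher at 1 h. At 8 h GH9C3 was 1.13 higher and GH9B13 1.07 higher at pH 6, while at 1 h GH9C3 was lower (-0.66) and GH9B13 did not pass the test (-0.03). Among trichome birefringence-like genes, TBL19 (1.13) and TBL21 (1.01) were higher at pH 6 at 8 h. At 1 h all signals of both genes were also higher at pH 6. For TBL19 they were 17.3, 21.8 and 22.7 at pH 6 against 5.73, 6.33 and 10.5 at pH 4.5. Of the 17 list members 1 passed the test at 1 h. Of 7 root hair genes 3 were higher and 0 lower at pH 6 at 8 h, with EXPA7 at 0.96 and AT2G47540 at 0.80 (median 0.36, camera adjusted p = 0.0587, and adjusted p = 0.370 with an estimated correlation). The list passed by camera with no filter (adjusted p = 0.0224), without replicates 1 or 2 of pH 4.5 (adjusted p = 0.0260 and 0.0312) or without replicate 3 of pH 6 (adjusted p = 0.0452). It also passed by fry (adjusted p = 0.00398).

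The chaperone gene Hsp70-2 was higher at 8 h than at 1 h by 2.19 at pH 4.5 and by 1.03 at pH 6. ATERDJ2B (AT4G21180), which encodes a DnaJ-type protein of the endoplasmic reticulum, was higher at 8 h by 0.73 at pH 4.5. Histone H2B genes HTB1 and HTB2 were higher at 8 h at pH 6 by 0.54 and 0.61, while at pH 4.5 HTB1 was lower at 8 h (-0.42), as was HTB4 (-0.55), and HTB2 did not pass the test (-0.04). HTB4 did not pass it at pH 6 (0.14).

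Early stress genes fell between 1 h and 8 h at pH 6 (median -0.83, 17 of 20 lower, adjusted p = 2.00e-13 with the preset correlation and 0.0532 with an estimated correlation) and did not pass the test at pH 4.5 (median -0.05, 4 higher and 6 lower, adjusted p = 0.435). The mean difference between the time effects, pH 6 minus pH 4.5, was -0.76, with an adjusted p of 1.58e-05 with the preset correlation and 0.137 with an estimated correlation.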
